A study of Mus musculus with 2 samples.

How the data were processed

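Total RNA of TgS1 cells was made into stranded total RNA libraries with the SMARTer kit for mammalian RNA and converted for DNBSEQ sequencing, per the labels' protocols. There were 2 libraries, 1 from long-term culture in DMEM and 1 from long-term culture in SCM. The groups were taken from the sample titles, and the columns of the table were matched to them by the name of the medium. The column names carry different replicate numbers, 1 for DMEM and 3 for SCM, and any other replicates are not analysed here. No other column of sample values was present.

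The deposited table gives FPKM values, a fragment measure scaled by gene length and library total, for 55323 rows with gene length, biotype and coordinates, per the file headers. The submitters' processing notes name Trim Galore, Trimmomatic 0.39, cutadapt 3.1, STAR 2.7.9a and featureCounts 2.0.1, and the genome builds GRCm38.p6 and mm10. The role and order of these tools, their parameters and the strand setting of the counting are not given in the sources used here. The gene lengths and other annotation columns of the table were used as the authors deposited them. The human TTR transgene has a row of its own, on a reference transcript of 616 bases, and 0 rows lie on the mitochondrial chromosome. Gene positions were compared with the GENCODE M21 annotation of GRCm38. Of 52046 matched gene identifiers, 1457 had the same position and 50022 had the same span at another position, so the build of the coordinates in the table could not be settled, and no coordinate was carried between builds.

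FPKM multiplied by gene length in kilobases summed to 1000000 in each library, and every such product was a whole multiple of a common step. Whole reads were therefore recovered, with 100% of rows within 0.01 of a whole read in both libraries. They summed to 29085791 reads in DMEM and 36666676 in SCM, over 21523 and 21508 rows with at least 1 read. The 10 most abundant rows took 7.15% of reads in DMEM and 7.74% in SCM. The FPKM steps gave these reads, but with 1 library per medium no count model was fitted.

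The measure was log2((FPKM in SCM + 1) / (FPKM in DMEM + 1)), with a pseudocount of 1 FPKM, for rows with at least 1 FPKM in 1 or both libraries. It understates the ratio of low genes. A row was called higher or lower at 2-fold on that scale. Fold values in the text are plain FPKM ratios, with 95% exact (Clopper-Pearson) intervals from the recovered reads and library totals. A comparison of reads of 2 libraries compares those libraries, not the conditions, and no p-value or SD was computed between media. The floor for a count of 0 was taken as 3 reads.

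The groups, the measure, the thresholds, the 39 gene lists, the rule for named genes and the alternative settings were set before the data were examined, apart from 2 alternatives added later (protein-coding rows alone, and lists without the genes they share with another list). The lists cover transthyretin and its partners, Schwann cell states, proliferation, lipids, matrix, signalling, stress, energy metabolism, immunity and markers of other cell types that a nerve-derived line could hold. For a list with at least 5 measured members, the percentile of its median was taken among 10000 random lists of the same size drawn from 20 bins of mean expression. Some lists share genes, and 13 of the 17 measured repair genes also stand in another list. The older symbols Ctgf and Cyr61 matched no row, and their present names Ccn2 and Ccn1 were used.

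The named genes were human TTR and mouse Ttr, then the 15 genes with the highest and the 15 with the lowest log2 ratio among those with at least 5 FPKM and 20 reads in the higher library. Predicted genes, mitochondrial genes, ribosomal protein genes, small RNAs and pseudogenes were left out of these. From each list, up to 4 members with the largest absolute log2 ratio were added, with at least 1 in each direction where members passed 2-fold in both. Other members of the lists named in the text, such as Sox10, Jun, Ngfr, Mbp, Ccnb2, Kif11, Uchl1, Btc, Asns, Id4 and Ddit4, were chosen after their values were seen. Some genes taken by the rule or by the lists are not reported here, nor drawn by name, though list counts and medians include them.

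The steps were tested on simulated reads for this comparison, with 200 genes given a known fold. The intervals held the true ratio in 95.65% of 12330 genes. Of 75 genes with a 4-fold difference and at least 5 FPKM, 100% were called, of 56 genes with a 1.5-fold difference 0%, and of 12134 unchanged genes 0.239%. The simulated reads carried counting noise alone, without variation between cultures or library preparations. These rates are therefore not error rates of the calls between the 2 media. Alternatives changed the pseudocount, the filter on low values, the scaling, the rows counted as genes, the unit, the fold threshold, the use of the counting interval, the bins of the random lists and the list summary. Similarity of pseudogene transcripts to mitochondrial transcripts was measured on the GENCODE M21 transcripts with BLAST 2.17.0. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.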

Results

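RNA was sequenced from TgS1 cells, a mouse Schwann cell line that carries a human transthyretin transgene and serves as a model of hereditary transthyretin (ATTR) amyloidosis. Schwann cells are the glia of peripheral nerves. The cells had been kept in long-term culture in DMEM, a standard basal medium, or in a medium that the labels call SCM and do not spell out. There was 1 library per medium, so no difference given here has a replicate check and no p-value is given. The DMEM library held 29085791 reads assigned to the rows of the table and the SCM library 36666676. At these depths a count of 0 would allow up to 0.103 FPKM in DMEM and 0.0818 FPKM in SCM for a gene of 1 kb. Intervals are 95% exact (Clopper-Pearson) intervals of the 2 read counts. Intervals and floors cover counting error only, because there was 1 library per medium. Amplified reads without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error.

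The comparison of SCM with DMEM bears on how human transthyretin expression varies with the state of the Schwann cell, in particular the repair state named in the series title. The labels do not say which medium was taken to give that state. Human TTR had the lowest log2 ratio on the log2(FPKM + 1) scale, with 461 FPKM (8262 reads) in DMEM and 5.84 FPKM (132 reads) in SCM, which is 78.9-fold lower in SCM (95% counting interval 66.4 to 94.4). Most genes of the amino acid response were lower in SCM as well, and the repair Schwann cell genes Ccl2, Gdnf, Fgf5, Uchl1 and Btc were at least 2-fold lower. All 13 measured genes of the TGF-beta target list lay below 0 in log2 ratio, and 3 of them were at least 2-fold lower. Most measured myelin protein and cholesterol synthesis genes lay above 0 in log2 ratio, and the type IV collagen genes Col4a1 and Col4a2 and the sodium pump gene Atp1b2 were at least 2-fold higher in SCM.

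Human TTR ranked 44 among all rows by FPKM in DMEM and 6007 in SCM, where it stood at 1.27% of its DMEM level. Its log2 ratio was -6.08. The table carries the human gene as a row of its own, on a reference transcript of 616 bases. The mouse gene Ttr (ENSMUSG00000061808), listed at chromosome 18, 20798337 to 20807378 on the plus strand, went the other way. It had 1.71 FPKM (59 reads) in DMEM and 5.73 FPKM (249 reads) in SCM, 3.35-fold higher (2.51 to 4.53). These are the coordinates of the authors' table, whose genome build could not be settled from the sources used here. Of the 8 genes of the list of transthyretin and its partners, 3 were measured. The remaining measured member was Lrp1, an endocytic receptor, at 8.25 FPKM in DMEM and 9.90 in SCM.

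Of 12334 rows with at least 1 FPKM in 1 or both libraries, 382 were at least 2-fold higher in SCM and 345 at least 2-fold lower, on the scale of log2(FPKM + 1). The other 11607 lay within 2-fold, and the median log2 ratio was -0.03. Of the rows called, 335 higher and 285 lower ones had a counting interval that excluded 1. Among protein-coding rows alone, a subset taken after the values were seen, 250 were higher and 145 lower of 10081. Of 209 microRNA rows 31 were higher and 66 lower, and of 130 small nuclear RNA rows 17 were higher and 38 lower. These short rows rest on few reads, 2552 and 2612 reads in all for microRNA and 2169 and 2658 for small nuclear RNA in DMEM and SCM, so these numbers of rows are imprecise. Across the 12334 rows the log2 values of both libraries correlated at r = 0.951, which is across genes, and genes are not independent replicates. In the 6137 rows with at least 5 FPKM in both libraries, the central 95% of log2 ratios ran from -0.80 to 0.82.

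**Figure D1:**
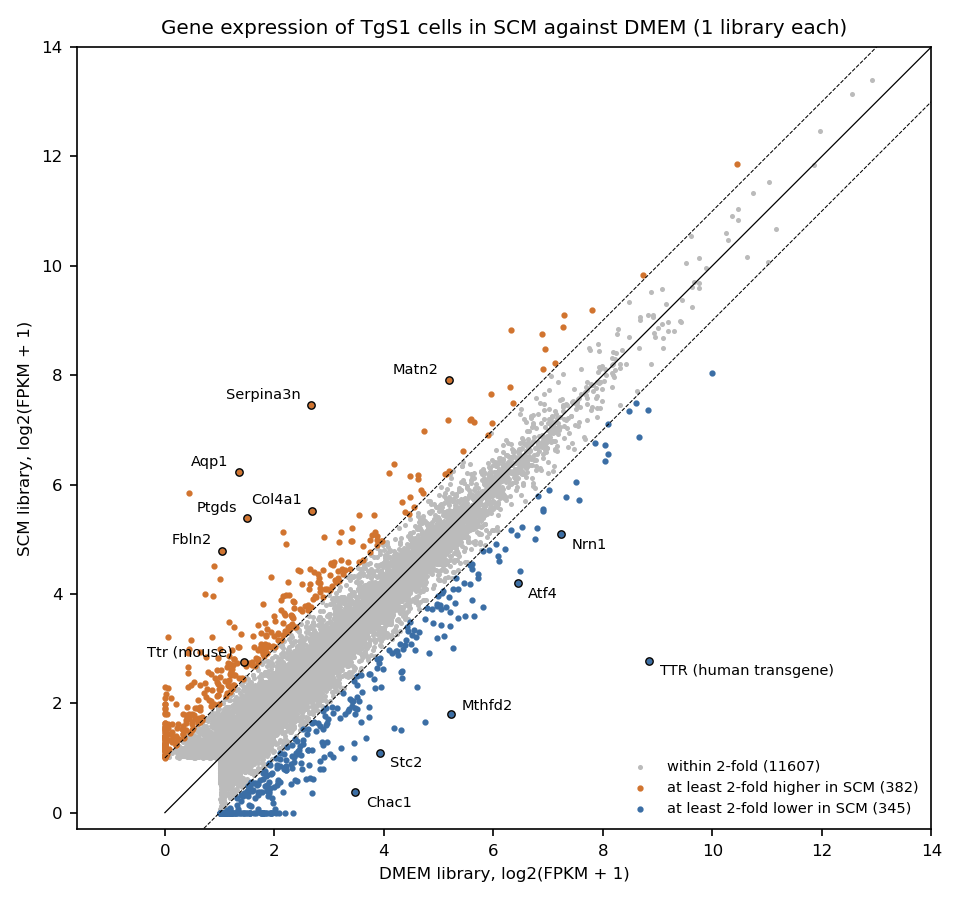
Expression of 12334 rows as log2(FPKM + 1) in the DMEM library (horizontal axis) and the SCM library (vertical axis), with orange points at least 2-fold higher in SCM (382), blue points at least 2-fold lower (345), grey points within 2-fold (11607) and dashed lines at 2-fold. Human TTR lies far below the lower line, at 461 FPKM in DMEM and 5.84 in SCM, and Aqp1 lies far above the upper line, at 1.56 and 74.2 FPKM.

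The genes with the highest ratios under the rule for named genes encode membrane transport, secreted and matrix proteins. Atp1b2, a beta subunit of the sodium pump, had 0.656 FPKM in DMEM and 15.1 in SCM and was 22.9-fold higher (18.3 to 29.1). The water channel gene Aqp1 was 47.6-fold higher (39.7 to 57.6), at 1.56 and 74.2 FPKM. Serpina3n, a serine protease inhibitor, had 5.40 FPKM in DMEM and 174 in SCM. Serpina3m, of the same gene family, had 2 reads in DMEM and 521 in SCM. Sharing of reads within this family was not measured, so their separate levels are uncertain. Ptgds, which encodes prostaglandin D2 synthase, had 1.83 and 41.0 FPKM, the matrix protein gene Fbln2 1.06 and 26.7 FPKM, and Ndrg2 0.860 and 21.8 FPKM. F3, the tissue factor gene, was 17.8-fold higher (14.2 to 22.8). Crabp1, a retinoic acid binding protein, had 9 reads in DMEM and 232 in SCM. Chl1, a cell adhesion gene, was 9.79-fold higher, Gdpd2 7.99-fold and the matrix gene Matn2 6.76-fold, from 35.6 to 240.5 FPKM.

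Below human TTR, the lowest ratios under the rule for named genes were those of Mthfd2, an enzyme of mitochondrial one-carbon metabolism, and Chac1, which degrades glutathione. Mthfd2 was 14.7-fold lower in SCM (13.1 to 16.5) and Chac1 33.9-fold lower (21.2 to 57.7). The secreted hormone gene Stc2 was 12.4-fold lower, the cationic amino acid transporter gene Slc7a1 10.1-fold and the chemokine gene Ccl7 8.87-fold. Tpbg had 11.8 and 1.57 FPKM. Pcdh20, a protocadherin gene, had 37.3 and 7.11 FPKM, and Nrn1, which encodes neuritin, 151 and 33.0 FPKM. Chl1, Gdpd2, Matn2, Col4a1, Col4a2, Nrn1 and Tpbg each overlap another tested row in the table, as do Ncam1, Gfra1, Ltbp1, Ctsb, Fkbp5, Tsc22d3, Fosl1, Sesn2, Gins2 and Mcam. The strand setting of the read counting is not given in the sources used here, so reads of overlapping rows may be shared.

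Gene lists had been fixed before the data were examined. For each of the 31 lists with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of the same size matched on expression, as a description of these libraries. The medians of 10 lists lay at or above the 97.5th percentile and those of 3 at or below the 2.5th. Lists of independently varying genes would give 1.55 lists in all. Genes of a list can vary together between any 2 cultures, and some lists share genes. The larger number is therefore not evidence of a difference between the media.

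The lists of myelin proteins and of Schwann cell identity had medians above 0. Of 19 myelin protein genes, 9 were measured, 4 of these were at least 2-fold higher and 0 lower, and the median of 0.94 lay above all 10000 random lists. Mal had 3.33 FPKM in DMEM and 13.8 in SCM, Gjc3, a connexin gene, 47.0 and 147 FPKM and Pmp22 6.78 and 16.0 FPKM. Mbp, a major myelin gene, had 83.7 and 73.5 FPKM. All 14 genes of the Schwann cell identity list were measured, with 3 higher, 1 lower and a median of 0.34 at percentile 99.96. Gpm6b had 154 FPKM in DMEM and 468 in SCM, Dhh was 3.07-fold higher (2.86 to 3.30) and Itgb4 had 0.941 and 4.25 FPKM, whereas Nes, the intermediate filament gene of immature cells, had 455 and 164 FPKM. Sox10, the lineage transcription factor, had 126 and 113 FPKM. Of the myelination transcription factors, 7 were measured and 0 were 2-fold apart, with a median of 0.12 at percentile 87.1.

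Repair Schwann cell genes were mostly lower in SCM. Of 22 genes, 17 were measured, 5 were at least 2-fold lower, 1 was higher and 13 lay below 0, and the median of -0.47 lay below all 10000 random lists. Gdnf, a neurotrophic factor, had 43.8 FPKM in DMEM and 11.0 in SCM, 3.97-fold lower (3.75 to 4.21). The chemokine gene Ccl2 had 48.8 and 11.0 FPKM, the growth factor gene Fgf5 33.3 and 8.35 FPKM, and Uchl1, a ubiquitin hydrolase gene, 189 and 51.5 FPKM. Ngfr, the low-affinity neurotrophin receptor gene, had 2061 and 1079 FPKM, and Jun, a central regulator of the repair state, 236 and 168 FPKM, both within 2-fold. Gfap went the other way, at 0.530 and 3.17 FPKM. The immature and Remak list overlaps this one and was mixed, with 3 of 14 measured genes higher, 2 lower and a median of -0.18 at percentile 6.16. Its higher members included Matn2 and Ncam1, an adhesion molecule gene that was 3.26-fold higher (3.20 to 3.32), and its lower members were Id2 and Id4. The neurotrophic factors and receptors were mixed too, with 2 of 10 higher, 2 lower and a median of 0.01 at percentile 66.9. There Gfra1, a GDNF co-receptor gene, had 223 FPKM in DMEM and 583 in SCM, and Igf1 1.03 and 3.89 FPKM.

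**Figure D2:**
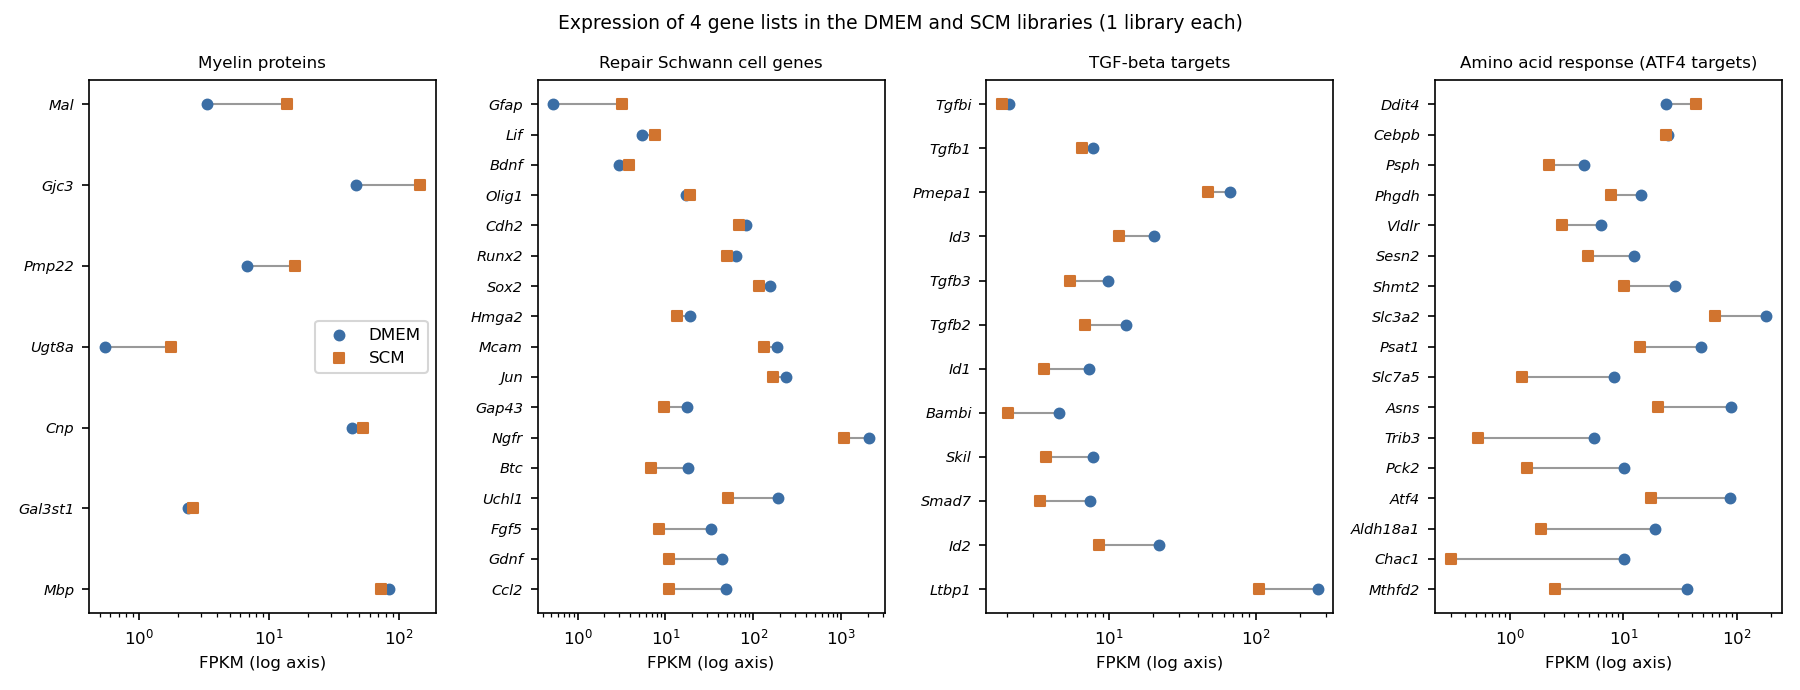
FPKM on a log axis of genes of 4 lists. Drawn are 7 of the 9 measured myelin protein genes and 17 of 17 repair Schwann cell genes. Also drawn are 12 of 13 genes of the TGF-beta target list, ligand genes included, and 17 of 17 ATF4 targets. Blue circles mark the DMEM library and orange squares the SCM library, joined by a line for each gene. Of the 7 myelin genes drawn 6 had a higher FPKM in SCM. Of the 17 repair genes 13, of the 12 genes of the TGF-beta target list 12 and of the 17 ATF4 targets 16 had a lower FPKM in SCM.

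Targets of ATF4, the transcription factor of the amino acid response, were mostly lower in SCM. Of 20 genes, 17 were measured, 12 were at least 2-fold lower and 0 higher, and the median of -1.71 lay below all 10000 random lists. Atf4 itself had 86.1 FPKM in DMEM and 17.3 in SCM, 4.97-fold lower (4.70 to 5.27). Beside Mthfd2 and Chac1, Aldh18a1, an enzyme of proline synthesis, was 10.1-fold lower, the pseudokinase gene Trib3 10.5-fold and Pck2, the mitochondrial phosphoenolpyruvate carboxykinase gene, 7.11-fold. Asns, which encodes asparagine synthetase, had 88.1 and 20.3 FPKM. Ddit4 was the measured member above 0, at a log2 ratio of 0.85. The medians of the other stress lists lay inside the central 95% of the random lists. Of 18 unfolded protein response genes, 0 were 2-fold apart and the median was -0.01 at percentile 62.6, with the chaperone gene Hspa5 at 120.5 and 163 FPKM. Heat shock genes had 0 of 13 members 2-fold apart and a median of -0.09 at percentile 28.7. NRF2 targets and antioxidants had 1 of 17 higher, 1 lower and a median of -0.07 at percentile 34.2. The lower member was the haem oxygenase gene Hmox1, at 39.8 and 10.8 FPKM, and the higher member Sod3. Cyclin-dependent kinase inhibitors and p53 targets had 1 of 16 higher (Sesn1), 1 lower (Sesn2, also an ATF4 target) and a median of -0.03 at percentile 53.9.

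All 13 measured genes of the TGF-beta target list lay below 0 in log2 ratio, and 3 were at least 2-fold lower. Their median of -0.85 lay below all 10000 random lists. The counting interval of the Tgfbi ratio (0.742 to 1.069) held 1. Besides targets, the list holds the ligand genes Tgfb1, Tgfb2 and Tgfb3. Ltbp1, a binding protein of latent TGF-beta at 262 and 105 FPKM, and Id2, at 21.9 and 8.56 FPKM, were among those past 2-fold, and the inhibitory Smad gene Smad7 had 7.35 and 3.40 FPKM. Of 11 measured targets of SRF and YAP, 0 were higher and 1 lower, Ccn1 at 6.39 and 0.729 FPKM, with a median of -0.23 at percentile 2.81. Collagens and basement membrane genes were higher on balance, with 6 of 21 measured genes higher, 2 lower and a median of 0.38 above all 10000 random lists. The type IV collagen gene Col4a1 was 8.21-fold higher (7.73 to 8.72) and Col4a2 4.96-fold higher (4.67 to 5.27). Both laminin beta chains differed in opposite directions, with Lamb1 at 16.1 FPKM in DMEM and 72.7 in SCM and Lamb2 at 35.9 and 11.7. Matrix proteases and inhibitors had 1 of 12 higher (Plat), 2 lower, among them Plaur, and a median of -0.05 at percentile 45.9.

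The 3 lists of lipid metabolism had medians above 0. Of 24 cholesterol synthesis genes, 22 were measured, 20 lay above 0, 2 were at least 2-fold higher and 0 lower, and the median of 0.52 lay above all 10000 random lists. Idi1, an isomerase of the mevalonate pathway, had 0.667 and 4.15 FPKM and Msmo1, a sterol oxidase gene, 14.4 and 30.4 FPKM. With a pseudocount of 3, 0 cholesterol genes passed 2-fold. Fatty acid synthesis genes had 1 of 15 higher and 0 lower, with a median of 0.23 at percentile 99.4. That gene was Scd1, the stearoyl-CoA desaturase gene, at 78.5 and 218 FPKM. Of 9 measured genes of adipogenesis and lipid storage, 4 were higher and 0 lower, with a median of 0.43 at percentile 99.8. These were the apolipoprotein genes Apoe, 4.94-fold higher (4.68 to 5.21), and Apod, at 1397 and 3738 FPKM, with Mylip and Abca1, targets of the liver X receptors. Glycolysis genes had 2 of 19 higher, Aldoc (1 read in DMEM and 416 in SCM) and Pdk1, and 0 lower. Their median was 0.22 at percentile 99.8, with 10 genes above 0 and 9 below. Pfkp, which overlaps another tested row, fell just short of the limit, at 10.2 and 4.62 FPKM. In plain FPKM it was 2.21-fold lower (2.10 to 2.33). Lysosome and autophagy genes had 2 of 20 higher and 0 lower, with a median of 0.18 at percentile 99.5, and the higher genes were Ctsb, a cathepsin gene at 119 and 275 FPKM, and Npc2. Nuclear genes of the respiratory chain had 0 of 22 members 2-fold apart and a median of -0.05 at percentile 40.2. Ribosomal protein genes had 0 of 20 and a median of -0.03 at percentile 50.8. None of the 13 mitochondrially encoded genes of their list was measured, because the table lists 0 rows on the mitochondrial chromosome.

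Cell cycle genes went both ways. Of 30 such genes, 19 were measured, 1 was higher and 0 lower, with a median of 0.09 at percentile 89.2. These genes were at low levels, where the pseudocount of 1 FPKM keeps ratios small. In plain FPKM the mitotic genes Mki67, Ccnb2, Cdk1, Top2a and Kif11 were 2.69-fold, 2.32-fold, 2.20-fold, 2.17-fold and 2.06-fold higher, and the replication gene Gins2 was 2.36-fold lower (1.97 to 2.84). The counting intervals of all these ratios excluded 1, and with a pseudocount of 0.1 the cell cycle list had 4 members higher and 1 lower. Wider groups, looked at after the results were seen, leaned the other way. The biological process term of mitotic cell cycle had 0 of 86 genes higher, 2 lower and a median of -0.13. That of mitotic sister chromatid segregation had 0 of 13 genes 2-fold apart and a median of -0.32. These mitotic genes therefore do not stand for mitotic genes at large. Replication-dependent histone genes had 0 of 9 members 2-fold apart and a median of -0.15, inside the central 95% of the random lists. Among signalling targets, immediate early genes had 2 of 17 higher, Dusp6 and Nr4a1, 1 lower, Fosl1, and a median of -0.17 at percentile 6.25. Dusp6, an ERK phosphatase gene, was 3.60-fold higher (3.27 to 3.97). Targets of cAMP and CREB had 1 of 11 higher (Nr4a1), 1 lower (Fosl2, at 32.0 and 9.82 FPKM) and a median of -0.05 at percentile 45.3. Insulin-FoxO and glucocorticoid targets had 3 of 16 higher, 2 lower and a median of 0.52 above all 10000 random lists. The glucocorticoid-induced genes Fkbp5 and Tsc22d3 were 4.05-fold and 2.40-fold higher. The 2 lower members were Igfbp3, at 17.7 and 6.76 FPKM, and Sgk1, also glucocorticoid-induced, at 3.12 and 0.829 FPKM.

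Immune genes were few. Interferon response genes had 2 of 14 higher, Ifit1 and Isg15, and 0 lower, with a median of 0.10 at percentile 91.4. Genes of MHC class I and II had 0 of 6 members 2-fold apart, all 6 above 0, and a median of 0.45 at percentile 98.6, with H2-D1 at 4.45 and 8.85 FPKM. Of 25 inflammatory cytokines and chemokines 4 were measured, with Ccl7 and Ccl2 lower and Csf1, a macrophage growth factor gene at 1.91 and 5.63 FPKM, higher.

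Most markers of other cell types were under the filter in both libraries. Of 15 macrophage markers 1 was measured, Cd68 at 1.34 and 1.45 FPKM, and of 16 neuron markers 1, Tubb3 at 60.2 and 45.0 FPKM. Of 20 fibroblast and perineurial markers 3 were measured and 0 were 2-fold apart. Of 14 hepatocyte and choroid plexus markers 0 were measured. Of 14 endothelial and pericyte markers 3 were measured, with Flt1 at 3.71 and 8.89 FPKM and Cspg4 at 0.314 and 1.84 FPKM both higher. The third, Mcam, also a repair gene here, was far more abundant and lower in SCM, at 185 and 134 FPKM, within 2-fold. Melanocyte and neural crest markers had 0 of 9 higher and 1 lower, with a median of -0.17 at percentile 14.5. The lower gene was Snai2, at 110.3 and 35.7 FPKM. Oligodendrocyte and astrocyte markers had 2 of 5 higher, Gfap and Aldoc, and 0 lower, with a median of 0.34 at percentile 96.9. The list median and mean differed in sign in 5 lists, which were transthyretin and its partners, the immature and Remak genes, the neurotrophic genes, the unfolded protein response and the nuclear respiratory chain.

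**Figure D3:**
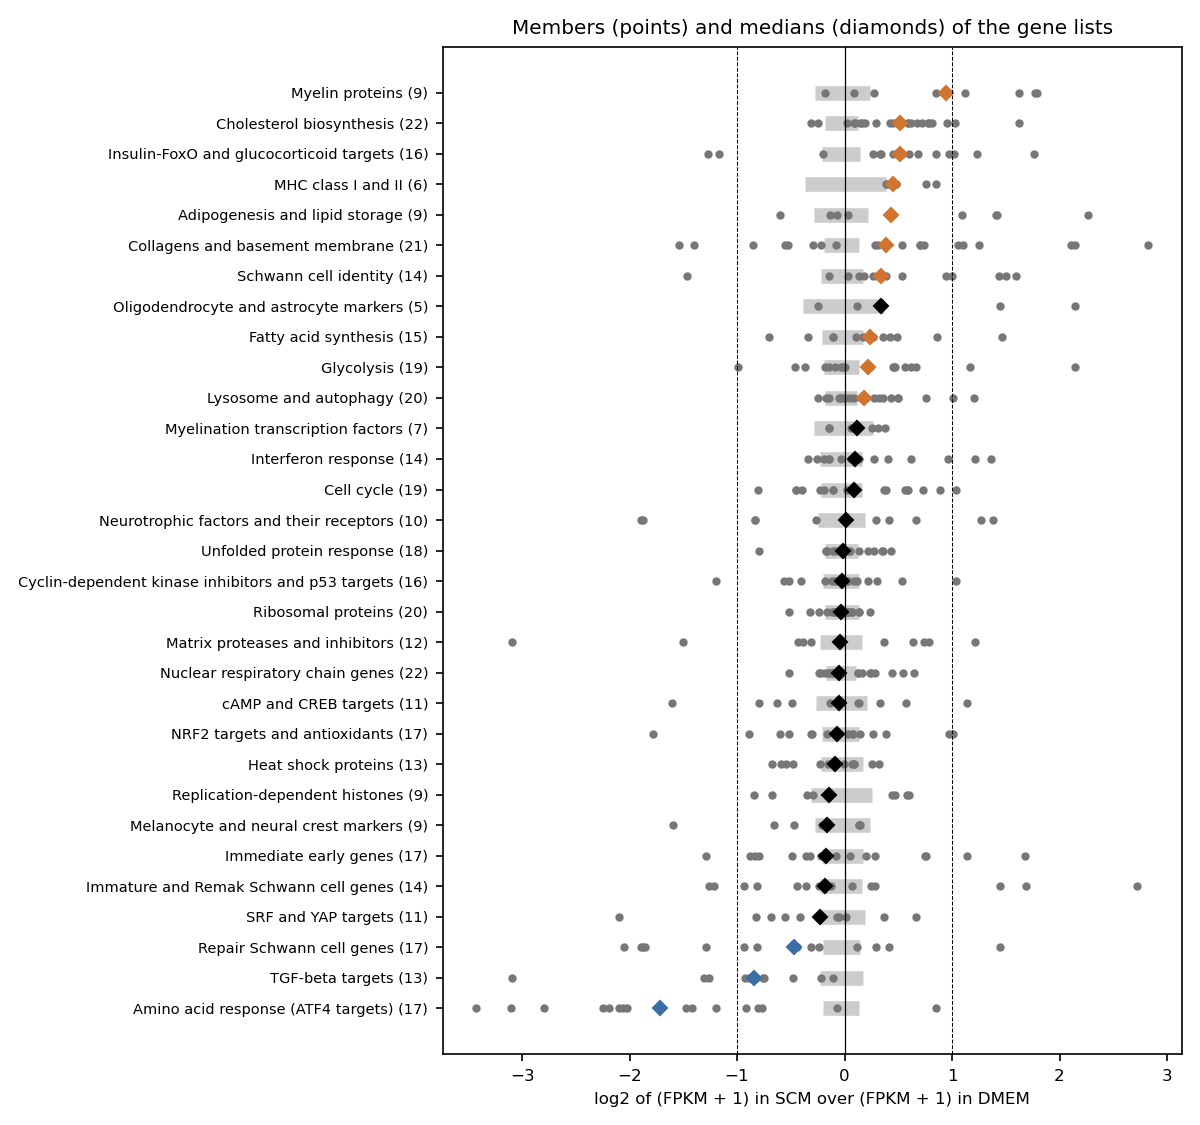
Log2 ratio of SCM over DMEM on the log2(FPKM + 1) scale for the 31 lists with at least 5 measured members, with points for genes, diamonds for list medians (orange at or above the 97.5th percentile of 10000 random lists, blue at or below the 2.5th, black otherwise), grey bars for the central 95% of random medians and dashed lines at 2-fold. The ATF4 target median of -1.71 and the TGF-beta target median of -0.85 lie lowest, and the myelin protein median of 0.94 lies highest.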

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

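In this part, the test of sequence identity between pseudogenes and mitochondrial transcripts was set before its result was seen, and the tests of human TTR, mouse Ttr and the respiratory chain genes were chosen only after the results were seen.

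Reads on pseudogene rows that resemble mitochondrial transcripts stood out because no gene list or named gene of the report covers them, although they are among the 12334 rows compared there. On 11 such rows of at least 95% identity, the share of the library was 2.27% in DMEM (660854 reads) and 3.30% in SCM (1209077 reads), a ratio of 1.45. Of the reads on all 55 rows that match a mitochondrial transcript, these 11 held at least 95.4% in each library, which is consistent with reads of mitochondrial transcripts being placed on nuclear copies when the mitochondrial chromosome has 0 rows. All 11 had a log2 ratio above 0 (Gm28438, at 1.11, passed 2-fold), with a median of 0.54 against -0.05 (SD 0.28 across genes) for nuclear respiratory chain genes, and this difference of 0.594 argues against a general rise of respiratory chain transcripts. Whether mitochondrial RNA itself differed between the media, or its share of the library preparation, stays open with 1 library each.

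Human TTR was 78.9-fold lower in SCM. Depth cannot account for it, since raw TTR reads were 62.6-fold fewer in the library with more reads, and over the scaling alternatives the log2 ratio nearest 0 was -6.04. Reads carried over from the DMEM library may supply part of the 132 TTR reads in SCM, because the lowest SCM level among the other genes used in this test, with at least 1000 reads in DMEM, was 6.83% (Mthfd2), above the 1.27% of TTR, so such a share cannot be told apart from expression. A loss of the transgene or a mixed-up culture cannot be told apart from an effect of the medium with 1 library per medium. An effect of SCM on the transgene's expression is therefore a hypothesis that stays open.

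Mouse Ttr was 3.35-fold higher in SCM. Human TTR reads counted on the mouse row do not account for its SCM level, because the DMEM proportion would give 0.943 reads where 249 were seen, 264 times as many. In DMEM there were 0.714 mouse Ttr reads per 100 human TTR reads, and whether these 59 reads came from the mouse gene or the transgene cannot be told apart without the reads. If they came from human TTR, the ratio of mouse Ttr could be larger than the value given. Rows within 20 kb reached a log2 ratio of at most 0.14 (B4galt6), which argues against a rise of neighbouring genes read into Ttr.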

How the results depend on the processing

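The protein-coding subset and the lists without shared genes were chosen after the data were seen. No paired analysis was possible because there was 1 library per medium, and for the same reason no library could be left out. Of 1326 values of 151 named genes, 926 moved by less than the distance from the estimate to the edge of its counting interval, 400 by more and 0 reversed. The 926 include all values under settings that changed only the filter on low values, which leave a gene's log2 ratio unchanged by construction. Of 442 values of list medians 27 moved and 0 reversed. The number of rows higher and lower was 382 and 345 as reported. It was 681 and 625 with a pseudocount of 0.1, 148 and 131 with a pseudocount of 3, and 210 and 165 with a filter of 5 FPKM. It was 974 and 928 at 1.5-fold, 38 and 28 at 4-fold, and 250 and 145 for protein-coding rows. Rescaling to TPM gave 1011 and 1145, and rescaling without ribosomal rows 1014 and 1160. In both, larger values make the same pseudocount and filter act on lower genes by construction. The latter setting was meant to drop mitochondrial rows too, but the table has 0 rows on the mitochondrial chromosome. The mitochondrial-like pseudogene rows stayed in. The human TTR log2 ratio was -5.71 with a pseudocount of 3. Myelin protein genes at least 2-fold higher numbered 2 with a pseudocount of 3. Repair genes at least 2-fold lower numbered 2 without shared genes. Cholesterol synthesis genes at least 2-fold higher numbered 4 with a pseudocount of 0.1 and 0 with a pseudocount of 3. They numbered 1 with a filter of 5 FPKM and 1 without ribosomal rows. Genes of the TGF-beta target list at least 2-fold lower numbered 6 with a pseudocount of 0.1, 7 with TPM and 7 without ribosomal rows. They numbered 6 with reads scaled to the library total and 1 without shared genes. Fewer rows tested do not by themselves explain the protein-coding counts, because calls were frequent among some of the rows left out. Of 209 microRNA rows 31 were higher and 66 lower, and of 130 small nuclear RNA rows 17 were higher and 38 lower. The threshold itself explains the counts at other folds, and fewer genes in a list those without shared genes. The cause of the other list counts was not tested. No list median changed its side of the percentile limits with 5 bins. Depth limits low genes most, such as Serpina3m with 2 reads in DMEM.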

Other observations

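The gene groups and tests in this part were chosen only after the results were seen. The table held 1531 biological process terms with 10 to 150 measured genes. Of these, 122 had medians at or above the 97.5th percentile of 1000 random lists and 73 at or below the 2.5th. Terms of independently varying genes would give 38.3 on each side. Terms share genes, and genes of a term can vary together, so these numbers describe the 2 libraries and not the media. Genes of potassium ion transport had a median of 0.25, with 8 of 39 at least 2-fold higher in SCM, 1 lower and most within 2-fold. Beside Atp1b2 and Aqp1 the higher genes included the pump regulators Fxyd1 (3.57 and 11.3 FPKM) and Fxyd3. They also included the glial inward rectifier channel Kcnj10 (0.0445 and 3.84 FPKM) and the voltage-gated channel Kcna2 (3.74 and 17.6 FPKM), while Kcna4 was lower (14.3 and 6.08 FPKM). Genes of cell-matrix adhesion had 5 of 36 higher, 1 lower and a median of 0.21. The laminin-binding integrin genes Itga6 (7.13 and 19.3 FPKM) and Itgb4 were higher, the integrin gene Itga8 was lower (5.46 and 2.12 FPKM), and Npnt, an integrin ligand, had 9.72 and 36.0 FPKM.

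Genes of microtubule-based process had 0 of 28 higher and 3 lower, with a median of -0.30. These 3 were Map1b (390 and 180.0 FPKM), Tubb6 (a log2 ratio of -1.16) and Tubb4a (11.2 and 3.62 FPKM). The larger term of microtubule cytoskeleton organization held the same 3 lower genes and 3 higher ones among 87, Gas2l3, Map7d2 and Tacc1, with a median of -0.16. Genes of mRNA splicing had a median of -0.14 over 115 genes and genes of rRNA processing -0.13 over 132, with 1 and 0 genes at least 2-fold lower. The nuclear long noncoding RNA Neat1 had 405 FPKM in DMEM and 116 in SCM, and Cd24a, a surface glycoprotein gene, 1015 and 261 FPKM. Lgi4, a secreted Schwann cell protein needed for peripheral myelination, had 117 FPKM in DMEM and 429 in SCM.

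A hypothesis on the ATF4 list is that ATF4-dependent transcription was lower in the SCM library. It was tested on tRNA synthetase genes, none of which is in the list. Of 12 measured synthetase genes known as ATF4 targets, 9 were at least 2-fold lower, with a median of -1.28 (range -1.88 to -0.41), among them Nars (108 and 31.0 FPKM) and Cars (19.2 and 4.50 FPKM). Of 8 other cytosolic and 15 mitochondrial synthetase genes 0 were 2-fold lower, and the median of the targets lay -1.16 from that of these 23, which is consistent with the hypothesis. Not all ATF4 targets followed. Ddit3 and Atf3, also known as ATF4 targets but placed in other lists, stayed within 2-fold, at 11.9 and 10.5 FPKM and 342 and 294 FPKM. A fall across the unfolded protein response list is argued against by its median of -0.0104. That median does not test single branches of the response. Which component of either medium might lie behind the difference was not tested.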
